A study of Caenorhabditis elegans with 60 samples.

How the data were processed

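The material was early embryos of Caenorhabditis elegans of 5 genotypes, with 3 chromatin preparations each and an input and an H3K9me3 library per preparation. Per the labels' protocols, chromatin was immunoprecipitated, libraries were amplified by polymerase chain reaction, and fragments were read from both ends on a HiSeq instrument. The labels contradict themselves at 2 points. The titles name H3K9me3 while the extraction protocol names an antibody against LEM-2, and the growth protocol states 2 biological replicates while the extraction protocol states 3. The titles and the table give 3 preparations per genotype, and these were used. The 60 records hold 2 runs per library, and the table has 1 column for each of the 30 libraries, so the runs appear there combined.

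The deposited values are raw counts per consecutive window of 500 bp, 1 column per library, as the values themselves show: whole numbers from 0, with a different total in every column. The genome build is ce10 per the labels. Neither the labels nor the file headers name the aligner, the counting tool or the handling of duplicates, so multiply mapped reads in repeats could be counted in more than 1 way. Of 200579 windows, 442 were not 500 bp long and 200572 held at least 1 count. Coordinates are given 1-based as in the table. Counts come from amplified fragments without molecular identifiers, so the number of counts overstates the number of independent molecules.

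The test fixed before the data were examined was limma on log2 enrichment. Because the table held counts, edgeR's quasi-likelihood test was used instead, and limma became an alternative. edgeR 4.0.16 in R 4.3.3 was run with TMM factors, which ranged from 0.475 to 1.24, and with 1 group per genotype and library type. Each contrast was the difference between genotypes of the difference between H3K9me3 and input. Adjusted p-values are Benjamini-Hochberg values over all windows tested, with a threshold of 0.05. The interaction is the change from nrde-3 to met-2 nrde-3 minus the change from lin-61 to lin-61 met-2. All 30 libraries entered the first fit under their labels, with no covariate.

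A second fit, chosen after seeing the data, is called the restricted set. It left out the input and H3K9me3 libraries of N2 replicate 1 and kept the 184148 windows whose mean input level differed by at most 1.5 times between the 5 genotypes, which removed 16424 windows. Its TMM factors ranged from 0.579 to 1.14. Where libraries are named by genotype the name is the label, and no library was moved to another group.

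Levels are log2 ratios of H3K9me3 over input per preparation, each on counts scaled to the library and with a pseudocount of 8 counts. Arms are the outer 0.333 of the length at each end of an autosome and the centre is the rest. The enriched set is the top 10% of windows by the mean over genotypes, weighted equally. Regions and set medians were compared per preparation by exact two-sided permutation tests with Benjamini-Hochberg adjustment within each family. Depth relative to other strains in a gap is the scaled depth over the median library of the same type.

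Loci were named by a rule fixed before the data were examined. Called windows of the same direction were joined across at most 1 other window, a locus needed at least 3 called windows, and every preparation of the one group had to lie on the same side of every preparation of the other. The 10 loci with the largest mean log2 change per comparison and direction were taken, and also the window with the largest change on each chromosome. Applying the rule to the restricted set was decided after seeing the data. Gene names were not assigned and the gene lists fixed in advance were not tested, because the annotation at hand is of WBcel235 and the table is of ce10.

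The scripts were tested on simulated counts with the real library sizes and 1 dispersion. Each window had 1 mean for all H3K9me3 libraries and 1 for all inputs, taken over all genotypes. Of these windows, 100 were changed by 2-fold and 100 by 4-fold between met-2 nrde-3 and nrde-3. No other differences between genotypes or preparations were simulated, so the false calls do not cover those in the real libraries. With all libraries and 200572 windows, 1 of the 2-fold and 46 of the 4-fold changes were recovered, with 2 false calls. In the restricted set of 184148 windows these were 76 and 100, with 4 false calls. The dispersion was 0.0636 with all libraries and 0.011 in the restricted set.

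Alternatives fixed before the data were examined covered scaling, pseudocount, filters, variance model, window size, threshold, the replicate number as a block and the omission of each preparation in turn. Added after seeing the data were limma 3.58.1 in the role of the test, DESeq2 1.42.0 and its size factors, library totals as scaling, a filter on low counts, evenly covered windows, the restricted set, and further omissions and scalings within it. Other splits of the preparations were tested on every 10th window. The overlap of calls along the chromosomes was compared with 1000 circular shifts. Figures were drawn with matplotlib.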

Results

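The data were H3K9me3 chromatin immunoprecipitation libraries and their inputs from early embryos of Caenorhabditis elegans, harvested before the bean stage. H3K9me3 is the trimethylated form of a lysine on histone H3 and marks silent chromatin. There were 5 genotypes: the wild type N2, the single mutants nrde-3 and lin-61, and the double mutants met-2 nrde-3 and lin-61 met-2. Each genotype had 3 chromatin preparations, and each preparation had an input and an H3K9me3 library, 30 libraries in all. NRDE-3 is an Argonaute that carries small RNAs into the nucleus, LIN-61 is an MBT-domain chromatin protein, and MET-2 is an H3K9 methyltransferase. According to the title of the series, the question was whether NRDE-3 and LIN-61 stand for 2 parallel ways of bringing the H3K9me3 enzyme to chromatin. The libraries of N2, nrde-3 and met-2 nrde-3 came from 1 library series and those of lin-61 and lin-61 met-2 from another, so differences across the series cannot be told apart from those of the lin-61 background.

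Depth ranged from 22265768 to 65845682 counts per library over windows of 500 bp on the ce10 genome, of which 200572 held reads. In the series with N2, inputs held 47874152 to 62101882 counts and H3K9me3 libraries 45137188 to 65845682. In the lin-61 series, inputs held 39698732 to 53498742 counts and H3K9me3 libraries 22265768 to 43856170. Windows without a count numbered 8 to 55 per library in the N2 series and 2386 to 3250 in the lin-61 series.

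Windows that were missing from some strains checked the labels. They were found from the inputs after the data were seen and were not assigned to genes, for want of an annotation of this build. On X, where the labels place the nrde-3 allele, the window 371736 to 372235 had a relative depth of 0.266 to 0.285 in the libraries labelled nrde-3 input and 0.225 to 0.247 in those labelled met-2 nrde-3 input. The H3K9me3 libraries of both labels were low there too, at 0.384 to 0.643 for nrde-3 and 0.199 to 0.325 for met-2 nrde-3. On III, where the labels place the met-2 allele, windows 8376067 to 8377566 were nearly empty in both library types of lin-61 met-2, at 0.059 to 0.077 for input and 0.072 to 0.244 for H3K9me3. The libraries labelled met-2 nrde-3 H3K9me3 were also low there, at 0.083 to 0.098, but those labelled met-2 nrde-3 input stood at 1.00 to 1.04. The libraries labelled nrde-3 input, from a strain without the met-2 mutation per the labels, were at 0.060 to 0.064, and those labelled nrde-3 H3K9me3 at 1.00 to 1.32. A gap on V, from 18443897 to 18465896, crossed the same way: 0.009 to 0.043 in met-2 nrde-3 input and 0.010 to 0.031 in nrde-3 H3K9me3, against 0.962 to 0.996 in nrde-3 input and 0.903 to 1.38 in met-2 nrde-3 H3K9me3. No window checked the lin-61 allele on I.

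**Figure D1:**
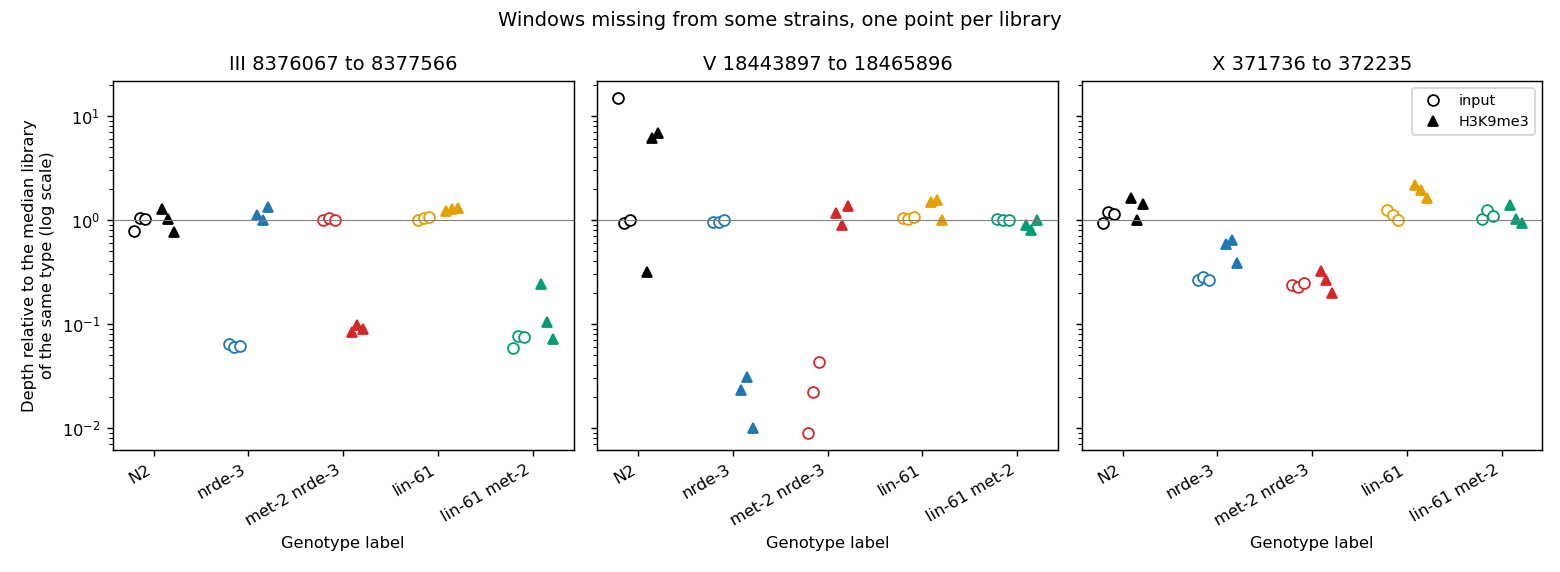
Depth in the windows missing from some strains, per library and relative to the median library of the same type (log scale), for input (open circles) and H3K9me3 (filled triangles) by genotype label. On III the inputs labelled nrde-3 lie at 0.060 to 0.064 while those labelled met-2 nrde-3 lie at 1.00 to 1.04, the reverse of the H3K9me3 libraries.

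A further contradiction lay in N2 replicate 1. In the library labelled N2 input 1 the level at the 99th percentile was 12.96 times the median window, against 1.26 to 1.73 in the other inputs. In the library labelled N2 H3K9me3 1 it was 1.71, against 2.53 to 22.88 in the other H3K9me3 libraries. The enrichment of N2 replicate 1 correlated with N2 replicates 2 and 3 across windows at r = -0.785 and -0.727, while replicates 2 and 3 correlated at 0.959. All labels were kept in the counts given first for each comparison. Beside each stands the count from a restricted set, chosen after seeing the data, without the 2 libraries of N2 replicate 1 and with only the 184148 windows whose inputs were evenly covered in all genotypes. Loci, regions and levels come from the restricted set, with 2 N2 preparations and 3 of every other genotype, and inputs were paired as labelled. Of the 46 loci ranked 1 to 3 in a comparison and direction, 20 also passed the test with all libraries as labelled. The other 26, which include every such loss against N2, nrde-3 or lin-61, kept their direction there but did not pass. The losses against N2 were also smaller as labelled. The largest in nrde-3, on V, was -0.446 as labelled and -2.51 in the restricted set. The losses against nrde-3 and lin-61 compare no N2 library. The largest was -3.485 as labelled and -3.496 in the restricted set against nrde-3, and -1.953 and -1.938 against lin-61. The fit as labelled shares its spread with N2 replicate 1, and the dispersion was 0.0636 there and 0.011 in the restricted set.

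In N2, H3K9me3 lay on the autosome arms. The mean log2 ratio of H3K9me3 over input was 0.72 ± 0.07 (SD, n = 2) in the arms, -0.26 ± 0.05 in the autosome centres and 0.05 ± 0.02 on X. Of the 31244 windows at a mean log2 of at least 1 in N2, 91.6% lay in the arms and 1.6% in the centres. The number of such windows was 16717 in nrde-3, with 92.9% in the arms, and 8948 in lin-61, with 92.4% in the arms. Single preparations, scaled with all libraries, gave 27904 and 32670 in N2 replicates 2 and 3, 10398 to 24878 in nrde-3 and 7524 to 11707 in lin-61. In the double mutants the map was different. Of 11729 such windows in met-2 nrde-3, 39.7% lay in the arms and 48.3% in the centres, and of 7500 in lin-61 met-2, 51.9% lay in the arms, 28.2% in the centres and 19.9% on X.

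**Figure D2:**
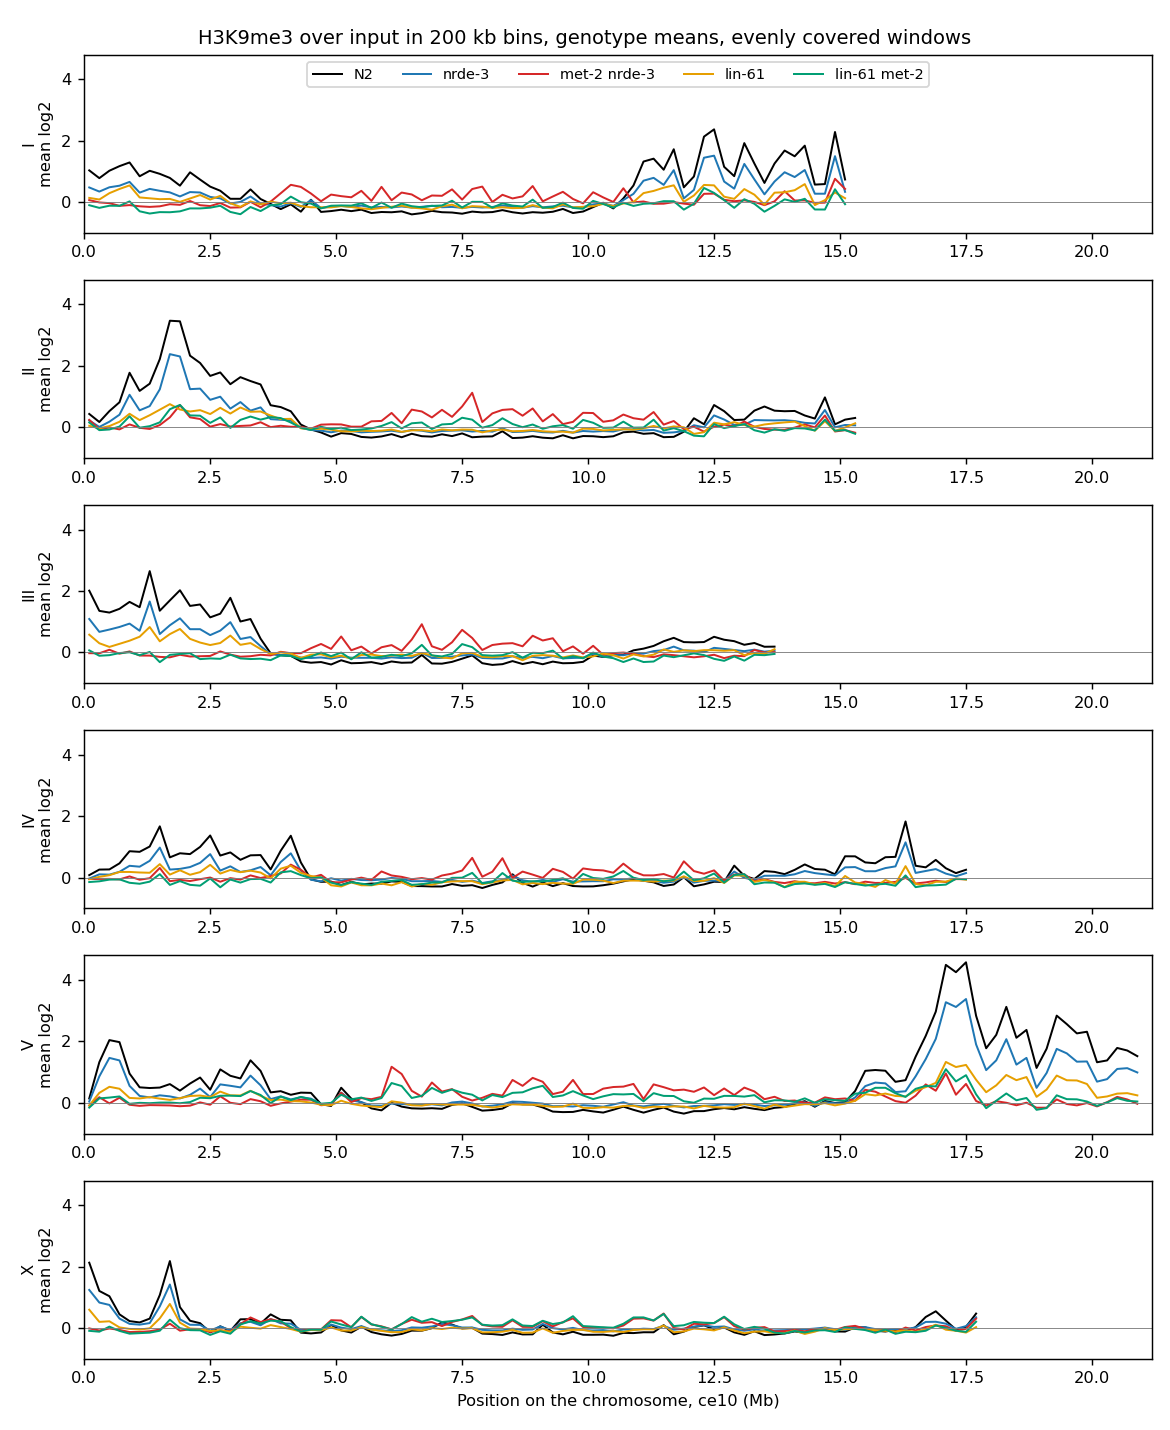
Mean log2 ratio of H3K9me3 over input in 200 kb bins along each chromosome (ce10, Mb), evenly covered windows, 1 line per genotype mean. N2 averages 0.72 in the arms and -0.26 in the centres, and met-2 nrde-3 averages 0.05 and 0.29.

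A set of 18415 enriched windows, the top 10% by the mean over all genotypes, summarised the level of the mark. The median over this set was 2.69 ± 0.20 in N2 (SD, n = 2), 1.69 ± 0.66 in nrde-3, 0.92 ± 0.13 in lin-61, 0.68 ± 0.05 in lin-61 met-2 and 0.39 ± 0.08 in met-2 nrde-3 (n = 3 each). Arms held 84.4% of the set. With all libraries as labelled, the N2 value was 1.23 ± 2.85 (n = 3), from -2.05 in replicate 1 and 2.74 and 3.01 in the others. No pair of groups overlapped in the restricted set, yet the exact two-sided permutation test gave p = 0.2 for the 4 comparisons with N2 (n = 2 against 3) and p = 0.1 for the other 3 (n = 3 against 3). These are the smallest values such groups allow, and all 7 were 0.2 after Benjamini-Hochberg adjustment. As labelled, only met-2 nrde-3 against nrde-3 reached the smallest exact p of 0.1 (n = 3 each, adjusted 0.7).

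**Figure D3:**
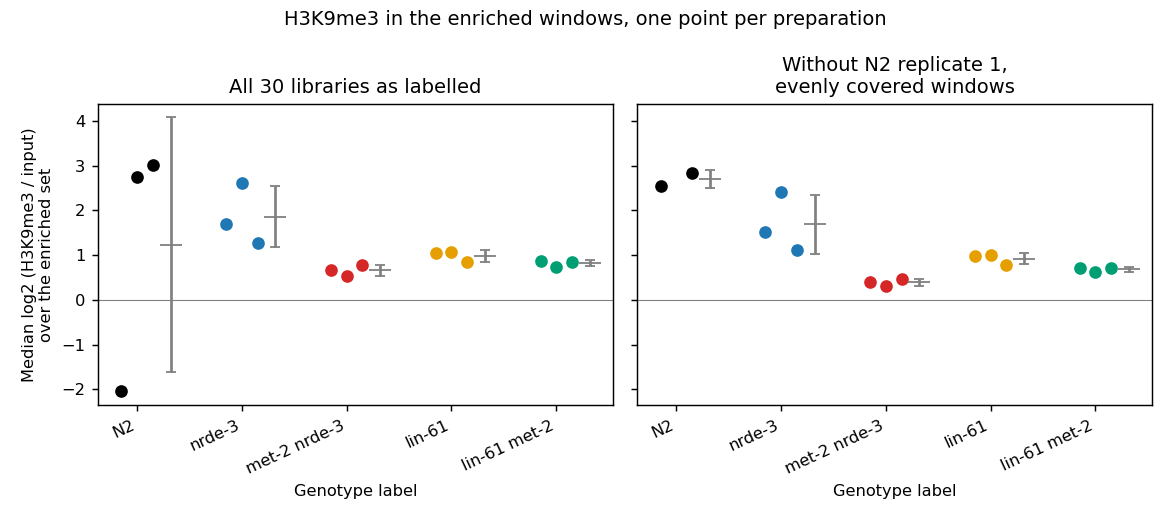
Median log2 ratio of H3K9me3 over input in the enriched windows, 1 point per preparation, with the mean and SD in grey beside the points, for all libraries as labelled (left) and the restricted set (right). N2 replicate 1 lies at -2.05 as labelled, while the N2 mean without it is 2.69.

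The comparison of nrde-3 with N2 asked how much H3K9me3 depends on the Argonaute. H3K9me3 was lower in nrde-3 at loci on the autosome arms. At V 1684969 to 1692968 the mean log2 ratio was 3.25 ± 0.21 in N2 (n = 2) and 0.76 ± 0.33 in nrde-3 (n = 3), a mean window change of -2.51 (median adjusted p = 6.43e-05, edgeR). At I 2147992 to 2155491 it was 2.34 ± 0.16 in N2 and 0.07 ± 0.07 in nrde-3, a change of -2.32 (8.89e-08), and at II 3290000 to 3307499 it was 3.82 ± 0.35 and 1.38 ± 0.53 (-2.42, 9.95e-04). With all libraries as labelled these changes were -0.446, -1.109 and -0.174 in the same order, and none passed. Of the 10 named loci that were lower, 8 lay in the arms and 5 on II. The only locus that was higher in nrde-3, X 372736 to 376735, lay next to the gap on X and stood at 1.72 ± 0.72 against 0.33 ± 0.08 in N2. It did not pass without N2 replicate 2 or 3, nor did the locus on II without N2 replicate 3.

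With all libraries as labelled, edgeR called 66 windows between nrde-3 and N2, 54 lower and 12 higher. In the restricted set it called 12775, of which 12510 were lower, with a median log2 change of -0.99, and 265 higher. The lower windows made up 12.2% of the arms, 0.24% of the centres and 1.2% of X, and joined into 1354 loci. The median change in the enriched set was -0.99, with 97.1% of its windows lower, against 0.65 with all libraries as labelled. The restricted count depended on single preparations: it was 5810 and 257 without N2 replicate 2 or 3, and 1413, 35595 and 1418 without nrde-3 replicate 1, 2 or 3. It was 196 when each preparation was divided by its own SD and tested by limma.

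The comparison of lin-61 with N2 asked the same of the MBT-domain protein. Here too the arms lost the mark, with most of the named losses on V. At V 17519401 to 17555900 the mean log2 ratio was 4.56 ± 0.24 in N2 (n = 2) and 1.03 ± 0.19 in lin-61 (n = 3), a change of -3.56 (median adjusted p = 7.17e-07, edgeR), while nrde-3 stood at 3.32 ± 0.76. At V 17643401 to 17646400 it was 4.56 ± 0.16 in N2 and 0.65 ± 0.24 in lin-61 (-3.93, 3.28e-07). All 10 named loci that were lower lay in the arms, 7 of them on V. Gains were smaller, the largest at I 3818485 to 3820484, from -0.38 ± 0.07 in N2 to 0.95 ± 0.08 in lin-61 (1.39, 6.66e-06).

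As labelled, edgeR called 625 windows between lin-61 and N2, 146 lower and 479 higher. The restricted set gave 53577, of which 43120 were lower at a median of -1.16 and 10457 higher at a median of 0.76. Lower windows made up 39.1% of the arms, 2.62% of the centres and 9.76% of X. Over all windows the median change was -0.13, so the balance of lower and higher calls is relative to that shift. Divided by the SD of each preparation and tested by limma, the same set gave 31144, with 24199 lower and 6945 higher. This division does not even out the contrast of the series. Scaled with all libraries, the SD was 0.527 to 0.585 in lin-61 and 0.505 in nrde-3 replicate 3. Their 99th percentiles were 2.53 to 3.38 and 5.66 times the median window. The count after division therefore cannot tell how much loss outlasts a difference in contrast, here or in other comparisons across the series. Without N2 replicate 3 the restricted count was 31748, and the genotypes came from different library series.

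Because both single mutants were set against the same N2 libraries, the overlap of their losses was compared with simulated groups that had no change. On every 10th window, 18415 in all, 1219 were lower in nrde-3, 4319 in lin-61 and 1093 in both. Independent lists of those sizes would share 286. The 5 simulations called at most 1 window lower, so their calls could not overlap, but lists of the same sizes taken from the lowest p-values in them shared 835 to 873. Across windows the changes of the single mutants correlated at r = 0.771, against 0.607 in the simulations, with a covariance of 0.265 against 0.034. A split control, chosen after seeing the data, set each single mutant against a different N2 preparation. Each comparison then held 1 N2 preparation, so only the changes are given and not the calls. With nrde-3 against N2 replicate 2 and lin-61 against replicate 3 the changes correlated at r = 0.701, and with the replicates exchanged at 0.576. The simulations gave -0.017 to 0.014, so the shared control alone did not give the correlation of the changes. Both mutants were flatter than N2, which could also align their losses, and the overlap was not tested after scaling. Of the 12510 windows lower in nrde-3 over the whole restricted set, 188 were still called after each preparation was divided by its SD. Most of the nrde-3 calls behind the overlap of 1093 windows thus depend on the scaling. Windows are also not independent replicates.

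The strongest N2 domains were counted by the level left in each mutant. Of 15097 windows at a mean log2 of at least 2 in N2, a choice that favours losses, 638 (4.2%) were below 1 in nrde-3 and 8067 (53.4%) in lin-61. In 7545 of them lin-61 was below 1 while nrde-3 was not, and in 116 the reverse held. This comparison crossed the library series, and the lin-61 series was flatter: its H3K9me3 libraries had a 99th percentile of 2.53 to 3.55 times the median window, against 5.66 to 16.26 in nrde-3. Lower contrast alone could put lin-61 windows below a fixed level, so these counts do not separate the mutants from the series. In the double mutants 12487 (82.7%) were below 1 in met-2 nrde-3 and 12236 (81.0%) in lin-61 met-2, with 11648 (77.2%) below 1 in both. Both double mutants were at 1 or more in 2022 windows (13.4%).

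Comparing met-2 nrde-3 with N2 and with nrde-3 asked what is left of H3K9me3 when NRDE-3 and MET-2 are both missing. At some loci on the right arm of V the mark fell to near the input level, though a bin of 200 kb from 17000001 still averaged 0.96 in met-2 nrde-3. At V 18744396 to 18764395 the mean log2 ratio was 4.78 ± 0.24 in N2 (n = 2), 3.44 ± 0.77 in nrde-3 and 0.11 ± 0.06 in met-2 nrde-3 (n = 3 each), a change of -4.72 against N2 (median adjusted p = 1.43e-09, edgeR) and of -3.50 against nrde-3 (1.23e-07). At X 119737 to 125236 the levels were 4.60 ± 0.12, 3.30 ± 0.82 and 0.10 ± 0.09. In the chromosome centres the mark appeared where N2 had little: at III 6746074 to 6772573, 26500 bp long, the ratio was 0.21 ± 0.04 in N2, 0.14 ± 0.12 in nrde-3 and 3.18 ± 0.29 in met-2 nrde-3 (3.03 against N2, 7.35e-10). II 7081484 to 7084482 lost the mark in nrde-3, from 2.10 ± 0.29 to 0.09 ± 0.22, and stood at 3.09 ± 0.45 in met-2 nrde-3.

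Of the 10 named losses against nrde-3, 8 lay on V and 2 on X, and of the 10 named gains 7 lay in autosome centres and 4 on III. Against N2, 42.1% of arm windows were lower and 5.29% higher, while 0.69% of centre windows were lower and 35.9% higher. Against nrde-3 these shares were 24.6% and 4.75% in the arms and 0.25% and 26.6% in the centres. The longest locus was 133500 bp among the losses against N2 and 56000 bp among the gains.

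As labelled, edgeR called 21512 windows between met-2 nrde-3 and N2, 3676 lower and 17836 higher, and 17631 between met-2 nrde-3 and nrde-3, 1398 lower and 16233 higher. The restricted set gave 71281 against N2, with 44763 lower (median -1.40) and 26518 higher (median 0.91), or 52319 by limma after division by the SD, with 32056 lower and 20263 higher. Against nrde-3 it gave 46749, with 26034 lower (median -1.15) and 20715 higher (median 0.97). Mitochondrial DNA, which has no nucleosomes, was higher in met-2 nrde-3 by 0.94 against N2 and by 0.99 against nrde-3, though none of its windows was called. The loci with the largest labelled changes between met-2 nrde-3 and nrde-3, III 8376067 to 8378066 at -9.29 and V 18443897 to 18465396 at 13.75, were the gaps in which the input labels cross.

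Comparing lin-61 met-2 with N2 and with lin-61 asked the same of the LIN-61 background. Little of the mark was left at single loci on the same arm of V, where the bin from 17400001 still averaged 0.90 in lin-61 met-2. At V 19317393 to 19325892 the mean log2 ratio was 4.70 ± 0.16 in N2 (n = 2), 1.52 ± 0.37 in lin-61 and 0.20 ± 0.13 in lin-61 met-2 (n = 3 each), a change of -4.51 against N2 (median adjusted p = 1.22e-08, edgeR). Against lin-61 the largest loss was at V 19041395 to 19044394, from 2.31 ± 0.38 to 0.40 ± 0.30 (-1.94, 0.00425). Gains were again frequent in centres: V 7073946 to 7081945 rose from -0.18 ± 0.04 in N2 to 1.80 ± 0.20 in lin-61 met-2 (2.03, 1.99e-06). The largest named gain against lin-61, V 6164450 to 6171449, lay in the left arm and rose from 0.20 ± 0.10 in lin-61 to 1.94 ± 0.16 (1.77, 1.06e-04). Of the 10 named losses against N2, 5 lay on V and 5 on X. Of the 10 named gains against lin-61, 6 lay in autosome centres, and of the 10 losses against lin-61 6 lay on V and 3 on III.

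As labelled, edgeR called 17115 windows between lin-61 met-2 and N2, 5067 lower and 12048 higher, and 9783 between lin-61 met-2 and lin-61, 2456 lower and 7327 higher. The restricted set gave 67821 against N2, with 47356 lower (median -1.33) and 20465 higher (median 0.79), or 53251 after division by the SD, with 37406 lower and 15845 higher. Against lin-61 it gave 25839, with 11781 lower (median -0.81) and 14058 higher (median 0.79). After division by the SD and limma it was 43115, and the balance turned to 23138 lower and 19977 higher. Lower windows against lin-61 made up 10.0% of the arms and 2.07% of the centres, and higher windows 3.5% of the arms and 10.7% of X, with a larger share in the centres (13.47%). These shares are of the edgeR calls. The comparison with N2 crossed the library series, and that with lin-61 did not. Without lin-61 replicate 1 or 2 the restricted count against lin-61 was 13331 or 14123.

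The windows that gained the mark on adding the met-2 mutation overlapped between the nrde-3 and lin-61 backgrounds. In the restricted set 6769 windows were higher in both comparisons, 32.7% of those higher in met-2 nrde-3 against nrde-3 and 48.2% of those higher in lin-61 met-2 against lin-61. Independent lists within the same regions would share 2263, and the highest of 1000 circular shifts along the chromosomes shared 2804. Lower in both were 5073, against 2475 and 3373, while 51 were lower in met-2 nrde-3 and higher in lin-61 met-2, and 205 the reverse. Across windows, which are not independent replicates, the changes correlated at r = 0.555 and rho = 0.444. As labelled, 3984 windows were higher in both, against 912 within regions and 1188 as the highest shift. Lower in both were 27, against 23 and 35, and 18 of the 1000 shifts shared as many. Of 130957 windows below 0.5 in N2 and both single mutants, 5870 reached 1 in met-2 nrde-3, 2090 in lin-61 met-2 and 1766 in both, where independence would give 94.

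**Figure D4:**
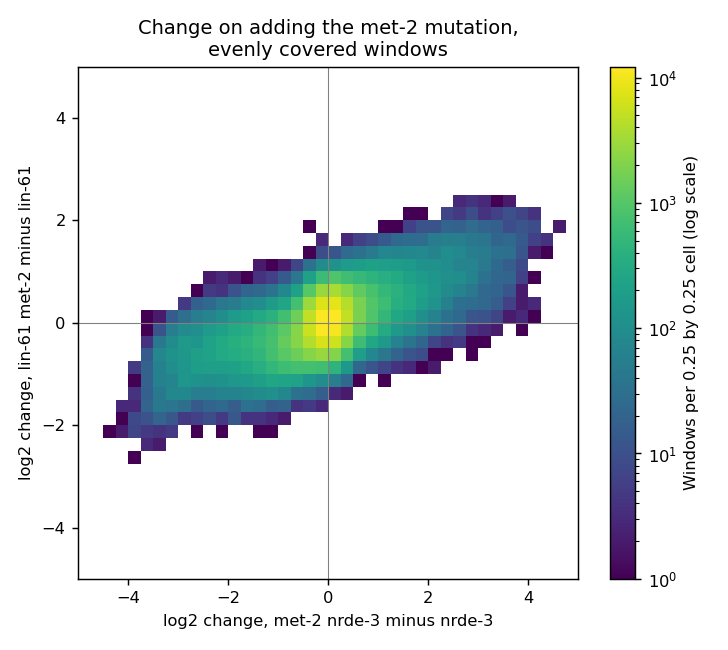
Log2 change in each evenly covered window on adding the met-2 mutation in the nrde-3 background (horizontal) and in the lin-61 background (vertical), coloured by the number of windows per cell (log scale). The changes correlate at r = 0.555 across 184148 windows.

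The double mutants also differed from each other, which asked whether NRDE-3 and LIN-61 leave different remains once MET-2 is gone. At III 6786074 to 6795073 the ratio was 3.14 ± 0.30 in met-2 nrde-3 and 0.89 ± 0.13 in lin-61 met-2 (n = 3 each), a change of -2.29 (median adjusted p = 1.17e-07, edgeR), and at IV 11969293 to 11996292 it was 2.85 ± 0.25 and 0.81 ± 0.06 (-2.10, 2.22e-07). Higher in lin-61 met-2 was II 3304500 to 3307499, at 1.15 ± 0.19 against -0.12 ± 0.06, where nrde-3 alone stood at 0.20 ± 0.19, lin-61 at 1.38 ± 0.34 and N2 at 4.20 ± 0.44. Of the 10 named loci higher in lin-61 met-2, 9 lay in arms and 6 on II. As labelled, edgeR called 7385 windows, 6269 lower in lin-61 met-2 and 1116 higher, and the restricted set gave 15663, with 13154 lower and 2509 higher. Division by the SD with limma gave 24691 there, with 17634 lower and 7057 higher. In the edgeR calls, lower windows made up 14.7% of the centres and 4.96% of the arms. The groups came from different library series, and without met-2 nrde-3 replicate 3 the restricted count was 8954. Lower windows had a median change of -0.90, while mitochondrial DNA, which has no nucleosomes, differed by -1.39 between the same groups. No mitochondrial window was called there.

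Whether the change on adding the met-2 mutation differed between backgrounds was tested by the difference of the within-series differences. It was negative on the right arm of V: at V 17556901 to 17563400 the ratio went from 3.13 ± 0.79 in nrde-3 to 0.23 ± 0.10 in met-2 nrde-3, and from 0.88 ± 0.26 in lin-61 to 0.71 ± 0.03 in lin-61 met-2 (n = 3 each), a difference of -2.89 (median adjusted p = 0.00164, edgeR). It was positive at III 9337063 to 9344562, where the ratio went from -0.19 ± 0.06 to 2.67 ± 0.37 in the nrde-3 background and from 0.50 ± 0.14 to 0.50 ± 0.05 in the lin-61 background (3.08, 2.25e-06). Of the 10 named loci with a negative difference 9 lay on V, and of those with a positive one 6 lay in autosome centres. As labelled, edgeR called 4659 windows, 390 negative and 4269 positive. The restricted set gave 18190, with 9101 negative at a median of -1.62 and 9089 positive at a median of 1.20. The restricted count was 11541 and 10595 without met-2 nrde-3 replicate 1 or 3, and 10397 without lin-61 replicate 3. Within-series differences cancel a shift common to a series but not a difference in contrast. The 99th percentile of the H3K9me3 libraries was 2.53 to 3.55 times the median window in the lin-61 series and 5.66 to 16.26 in nrde-3. At the locus on V, lin-61 at 0.88 also had less mark to lose than nrde-3 at 3.13. The negative differences may in part reflect these limits. Lower contrast limits the positive differences too. The 99th percentile was 7.01 to 10.92 times the median window in met-2 nrde-3 and 2.87 to 3.55 in lin-61 met-2.

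**Figure D5:**
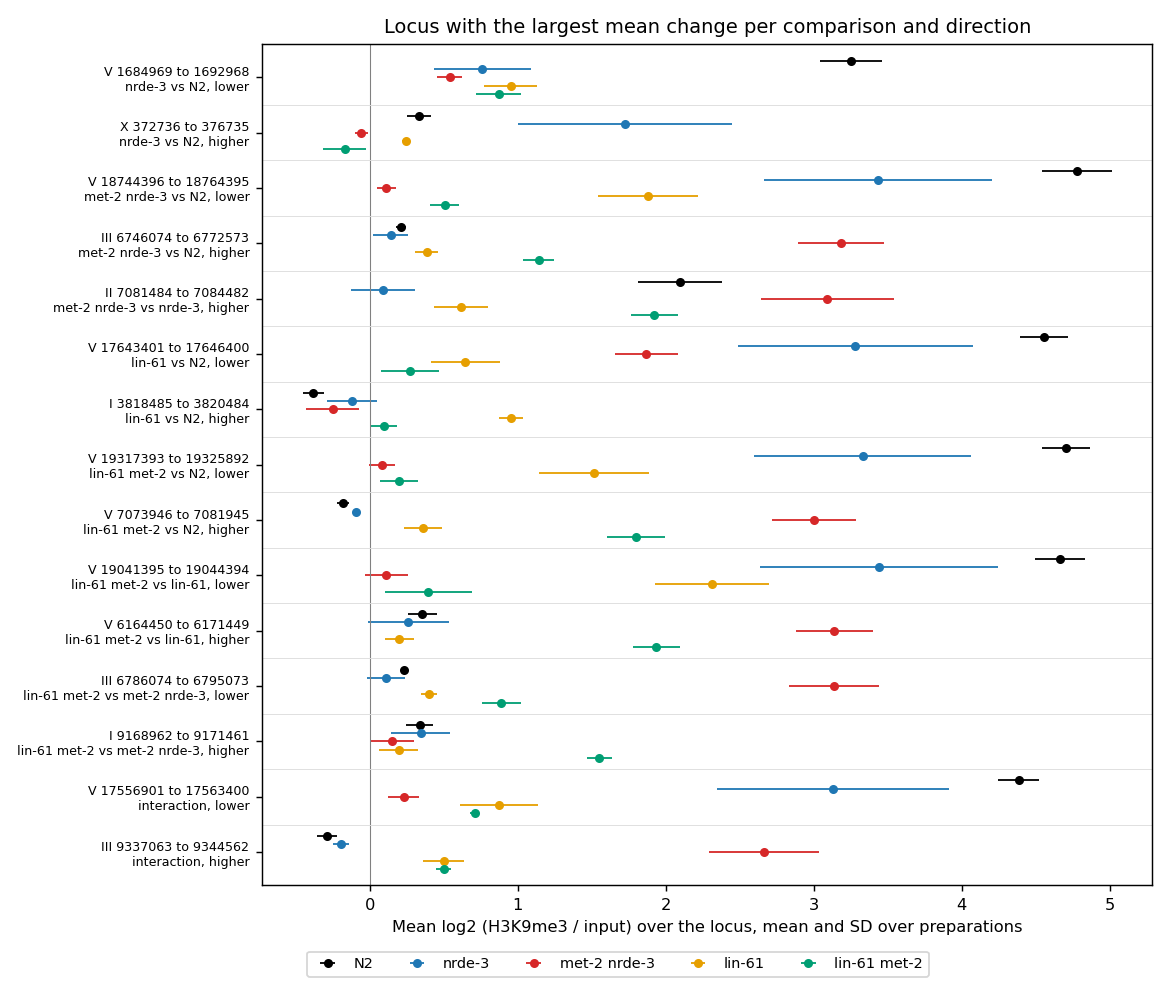
Mean log2 ratio of H3K9me3 over input (horizontal, points with SD over preparations) by genotype at the locus with the largest mean change per comparison and direction in the restricted set. At V 18744396 to 18764395, for example, N2 lies at 4.78 and met-2 nrde-3 at 0.11.

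Regions fixed in advance were summarised per preparation. The last 20 kb of I, at the ribosomal DNA repeats, kept 14 of its 40 windows in the restricted set and stood at 2.12 ± 0.16 in N2 (n = 2), 1.17 ± 0.42 in nrde-3, 0.43 ± 0.09 in met-2 nrde-3, 0.24 ± 0.10 in lin-61 and 0.26 ± 0.14 in lin-61 met-2 (n = 3 each). The outermost 500 kb of the chromosomes stood at 0.76 ± 0.08, 0.43 ± 0.19, 0.03 ± 0.01, 0.11 ± 0.05 and -0.05 ± 0.05 in the same order. The distal piRNA-rich region of IV stood at 0.48 ± 0.01 in N2, 0.24 ± 0.17 in nrde-3 and between -0.21 ± 0.08 and -0.14 ± 0.07 in the other genotypes. The proximal one stood at -0.19 ± 0.06 in N2, -0.07 ± 0.09 in nrde-3, -0.01 ± 0.01 in met-2 nrde-3, -0.20 ± 0.02 in lin-61 and -0.15 ± 0.04 in lin-61 met-2. Arms averaged 0.39 ± 0.17 in nrde-3, 0.14 ± 0.05 in lin-61, 0.05 ± 0.01 in met-2 nrde-3 and -0.01 ± 0.05 in lin-61 met-2, and centres -0.12 ± 0.06, -0.13 ± 0.04, 0.29 ± 0.05 and 0.03 ± 0.01. X lay between -0.04 ± 0.01 in lin-61 and 0.07 ± 0.02 in met-2 nrde-3. With all libraries as labelled, the difference of nrde-3 from N2 had the opposite sign: 0.67 instead of -0.96 in the last 20 kb of I, 0.29 instead of -0.24 in the distal piRNA-rich region, 0.16 instead of -0.33 in the outermost 500 kb, 0.14 instead of -0.33 in the arms and 0.12 instead of -0.17 over the autosomes. In the last 20 kb of I the change from nrde-3 to met-2 nrde-3 was -1.70 as labelled and -0.74 in the restricted set, and that from lin-61 to lin-61 met-2 was -0.51 and 0.021. No exact permutation test of a region passed 0.05 after adjustment, the smallest adjusted p being 0.262 for arms, centres and X (21 tests) and 0.247 for the other regions (42 tests), and groups of this size (n = 2 or 3) cannot reach 0.05. Mitochondrial DNA gave differences measured the same way: 0.99 between met-2 nrde-3 and nrde-3, from -0.82 ± 0.73 to 0.18 ± 0.06, and -1.39 between lin-61 met-2, at -1.21 ± 0.04, and met-2 nrde-3. None of its 19 windows was called in these comparisons, and single nrde-3 preparations ran from -1.361 to 0.017. The source of these differences was not tested.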

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

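The tests of the labels were chosen after the results were seen, while the interaction test and the counts over other splits of the preparations were fixed before the data were examined.

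The change on adding the met-2 mutation differed between the nrde-3 and lin-61 backgrounds, by edgeR's interaction test, in 4659 windows as labelled and in 18190 in the restricted set. The named loci with the most negative difference were V 17556901 to 17563400 (-2.89), V 17605401 to 17611900 (-2.79) and V 17427402 to 17462400 (-2.74), where the mark fell further in the nrde-3 background, from a higher level. The most positive were III 9337063 to 9344562 (3.08), II 12919458 to 12922957 (2.66) and III 6786074 to 6795073 (2.60), where the gain was larger in the nrde-3 background. Differences of both signs are subject to the lower contrast of the lin-61 series. The 3 on V did not pass with all libraries as labelled, although their differences there were -2.89, -2.80 and -2.73. On every 10th window the real grouping gave 449 windows, and 3 of 37 drawn splits gave as many, the real one included. At 3 of 37, chance is not excluded for the count as labelled. The highest other split gave 1071, and both of the others kept or mirrored the real grouping of the nrde-3 and met-2 nrde-3 preparations. They thus still carry that real difference. All splits that kept or mirrored this grouping and regrouped the lin-61 side gave 1071, 907, 420 and 315 windows, against 449. The splits that broke this grouping gave at most 2 windows, but they also removed the change in the nrde-3 background. Their low counts therefore cannot show that the backgrounds differ.

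For the pairwise comparisons, 10 splits of the 6 preparations are too few for a share under 0.05. By edgeR, the real and highest other counts on every 10th of 200572 windows were 6 and 5382 for nrde-3 against N2, 2175 and 4043 for met-2 nrde-3 against N2, 71 and 4402 for lin-61 against N2, and 1782 and 4781 for lin-61 met-2 against N2. As many windows came from 2, 4, 4 and 4 of the splits, the real one included, and every such other split separates N2 replicate 1 from N2 replicates 2 and 3, a structure of the samples. The real and highest other counts were 1781 and 0 for met-2 nrde-3 against nrde-3, 1002 and 0 for lin-61 met-2 against lin-61, and 738 and 0 for lin-61 met-2 against met-2 nrde-3, each with 1 split as large, the real one.

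Enrichment in N2 replicate 1 ran against that in N2 replicates 2 and 3. A failed immunoprecipitation would leave both of its libraries flat, but the library labelled N2 input 1 had a 99th percentile 12.96 times its median window, which argues against it. A candidate explanation is that the input and H3K9me3 libraries of this preparation carry each other's name, and 2 of 2 were out of place for their label. The gaps on III and V lay in different strains in input and H3K9me3 libraries: an exchange of the H3K9me3 libraries of nrde-3 and met-2 nrde-3 is argued against by a relative depth of at least 1 on III in those labelled nrde-3 H3K9me3, while all 6 inputs showed the pattern of the other label's H3K9me3 libraries, so the input names may be exchanged. No biological explanation was tested for either, and whether the exchange arose in the libraries, the table or the labels stays open.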

How the results depend on the processing

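All alternatives that bear the words restricted, limma on log2 enrichment, DESeq2, library totals or evenly covered were chosen after seeing the data, and the others were fixed before the data were examined. Of 184 alternative counts of called windows, 91 stayed within 1.5 times the count as labelled and 93 moved, and of 120 counts without 1 preparation 83 stayed and 37 moved. Median changes stayed within the spread in 53 of 56 alternatives, arms and centres in 71 of 84 and other regions in 30 of 36, as did all 615 such values without 1 preparation. That spread is wide where N2 replicate 1 enters, so 12 of these alternatives and 15 of these values without 1 preparation turned direction within it. No named locus changed direction in 721 alternatives. Of these, 674 left out 1 preparation, and 663 of them kept their side of the threshold. The naming rule had required every preparation of a group to lie on the same side, so an omission was unlikely to turn the direction. Of the 47 other alternatives, 21 kept their side of the threshold and 26 did not. Limits are the 2 usable N2 preparations, the lower depth of the lin-61 series and the library series shared with the lin-61 background. A further limit is the inputs of nrde-3 and met-2 nrde-3, which every fit paired as labelled although their names may be exchanged. No fit with these inputs exchanged was run. The restricted set does not remove this limit, as its windows could still differ in input by up to 1.5 times. Windows without a count also differed between the series, and depth alone does not account for it. The library lin-61 input 2 had 53498742 counts and 2386 such windows, and nrde-3 input 1 had 48369402 and 18. Whether both series were mapped and counted alike is not known. Except where fewer windows were tested, the cause of the moved counts and levels was not tested.

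Without N2 replicate 1 alone, edgeR called 13640 windows for nrde-3 vs N2, 83074 for met-2 nrde-3 vs N2, 53312 for met-2 nrde-3 vs nrde-3, 59073 for lin-61 vs N2, 77204 for lin-61 met-2 vs N2, 26235 for lin-61 met-2 vs lin-61, 15634 for lin-61 met-2 vs met-2 nrde-3 and 19128 for the interaction, in each the highest count without 1 preparation. The lowest were, in the same order, 42 (without nrde-3 replicate 1), 13200 and 12058 (met-2 nrde-3 replicate 3), 51 (lin-61 replicate 1), 7946 (N2 replicate 2), 3700 (lin-61 replicate 1), 3400 (met-2 nrde-3 replicate 3) and 2417 (nrde-3 replicate 1). Other counts past 1.5 times for lin-61 vs N2 were 68 and 371 without N2 replicate 2 or 3, 335, 381 and 302 without each nrde-3, 342, 365 and 350 without each met-2 nrde-3, 123 and 76 without lin-61 replicate 2 or 3, and 1157 without lin-61 met-2 replicate 1. For lin-61 met-2 vs N2 they were 8197 and 10169 (N2 replicate 3, lin-61 met-2 replicate 1), and for lin-61 met-2 vs lin-61 4043, 5161, 5987 and 6193 (lin-61 replicate 2 or 3, lin-61 met-2 replicate 1 or 3). For the double mutants the other was 4497 (met-2 nrde-3 replicate 1), and for the interaction 2991, 2664, 3055 and 2622 (nrde-3 replicate 2, met-2 nrde-3 replicate 3, lin-61 replicate 1 or 3). The median change of nrde-3 against N2 in the enriched set ran from -0.97 without N2 replicate 1 to 1.52 without N2 replicate 3, against 0.65 as labelled. Those of the other 3 mutants against N2, all negative as labelled, turned positive without N2 replicate 2 or 3, at 0.21 and 0.32 for met-2 nrde-3, 0.55 and 0.65 for lin-61 and 0.35 and 0.47 for lin-61 met-2.

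In the same order, the restricted set gave 12775, 71281, 46749, 53577, 67821, 25839, 15663 and 18190. With limma there it gave 12358, 68891, 44909, 51540, 67016, 25339, 12719 and 17634, and with limma after division by the SD 196, 52319, 46410, 31144, 53251, 43115, 24691 and 24796. Under that last scaling the double mutants split into 17634 lower and 7057 higher, against 13154 and 2509 without it. The split for lin-61 met-2 vs lin-61 turned from 11781 and 14058 to 23138 and 19977, and that for the interaction was 12405 and 12391, against 9101 and 9089. Evenly covered windows alone left 0 for nrde-3 vs N2 by edgeR, with 7683 at an unadjusted p under 0.05, against 12358 by limma in the restricted set.

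With fewer windows tested, the enriched set alone gave 0, 3415, 3312, 2, 1990, 990, 1516 and 999 by edgeR, where the 0 goes with 142 windows at an unadjusted p under 0.05. Windows of 2 kb gave 30, 10904, 7348, 10392, 6041, 3610 and 2532 for all but lin-61 vs N2. Fits with only the groups of the comparison, over all 200572 windows but with fewer libraries, gave 4, 10820, 53540, 0, 7, 25528, 16039 and 18362. That 0, for lin-61 vs N2 by edgeR, goes with 17125 windows at an unadjusted p under 0.05. Where N2 took no part, the counts 53540, 25528, 16039 and 18362 stood near the 53312, 26235, 15634 and 19128 without N2 replicate 1. Both kinds of fit leave that preparation out of the shared spread.

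At an adjusted p threshold of 0.01 the counts were 13053 for met-2 nrde-3 vs N2, 49 for lin-61 vs N2, 6235 for lin-61 met-2 vs N2, 2915 for lin-61 met-2 vs lin-61, 3476 for lin-61 met-2 vs met-2 nrde-3 and 2014 for the interaction. With a log2 change of at least 1 they were 12471, 366, 7273, 3640 and 4269 for the first 5 of these. For the same 6 results, limma gave 13724, 0, 2983, 765, 2324 and 783, with the pseudocount halved 13638, 0, 3145, 790, 2276 and 706, and with it doubled 13896, 0, 2759, 652, 2478 and 828, as well as 42 for nrde-3 vs N2. The 0 for lin-61 vs N2 in these 3 fits goes with 19124, 19073 and 19188 windows at an unadjusted p under 0.05, while DESeq2 called 1292. DESeq2 also gave 125 for nrde-3 vs N2 and 30877 for met-2 nrde-3 vs nrde-3.

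Scaling moved both counts and splits, given here as lower and higher. Library totals gave 65 and 2 for nrde-3 vs N2, 12402 (4060 and 8342) for met-2 nrde-3 vs N2, 11616 and 10093 for met-2 nrde-3 vs nrde-3, 112 (1 and 111) for lin-61 vs N2, 4900 (554 and 4346) for lin-61 met-2 vs N2, 1598 (728 and 870) for lin-61 met-2 vs lin-61, 978 (601 and 377) for the double mutants and 679 for the interaction. Quantile normalization with limma gave 56 and 2 for nrde-3 vs N2, 33164 (13841 and 19323) for met-2 nrde-3 vs nrde-3, 12 and 593 for lin-61 vs N2, 8940 (1122 and 7818) for lin-61 met-2 vs N2, 4128 and 6638 for lin-61 met-2 vs lin-61, 3835 for the double mutants and 1448 for the interaction. Division by the SD with limma gave 733 and 13791 for met-2 nrde-3 vs N2, 376 (168 and 208) for lin-61 vs N2, 5902 and 7871 for lin-61 met-2 vs N2, and 16510 (6167 and 10343) for lin-61 met-2 vs lin-61. DESeq2's size factors gave 156 and 262 for lin-61 vs N2. As labelled, the splits were 54 and 12, 3676 and 17836, 1398 and 16233, 146 and 479, 5067 and 12048, 2456 and 7327, 6269 and 1116, and 390 and 4269.

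Among levels, the restricted set turned the median change of nrde-3 against N2 from 0.65 to -0.99, its arms from 0.14 to -0.33 and X of lin-61 against N2 from 0.043 to -0.09. The median change of lin-61 met-2 against lin-61 was -0.43 over windows at 1 or more in N2 and -0.29 in the restricted set. That of lin-61 met-2 against met-2 nrde-3 was -0.21 as a mean, the reverse of the median. With outer quartiles as arms, arms changed by -0.53 and -0.22 and centres by 0.345 and 0.132 for met-2 nrde-3 vs nrde-3 and lin-61 met-2 vs lin-61. With medians in place of means, arms gave -0.19 for met-2 nrde-3 vs nrde-3 and 0.058 (reversed) for the double mutants, and centres 0.30 for met-2 nrde-3 vs N2, 0.25 for met-2 nrde-3 vs nrde-3, 0.12 for lin-61 met-2 vs lin-61 and -0.087 for the double mutants. X gave 0.076 for the double mutants, the outermost 500 kb -0.25 and autosomes -0.011 for met-2 nrde-3 vs nrde-3, and the last 20 kb of I -0.26 for lin-61 met-2 vs lin-61. Centred preparations gave 0.16 in centres for lin-61 met-2 vs N2 and -0.014 (reversed) on X for the double mutants. In the restricted set the last 20 kb of I gave -0.74 for met-2 nrde-3 vs nrde-3 and 0.021 (reversed) for lin-61 met-2 vs lin-61, and mitochondrial DNA 0.23 for the latter.

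The preparations share only a replicate number. Same-numbered preparations deviated together at r over 0.1 in 11 of 30 pairs (-0.814 to 0.767), and 28 of 60 correlated best with their own number. In the restricted set these were 7 of 26 (-0.202 to 0.42) and 20 of 52. With the replicate number as a block the counts were 61, 20215, 16482, 642, 15924, 8793, 6897 and 4175, all within 1.5 times. The gene lists and their alternatives were not run, for want of an annotation of the same build.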

Other observations

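All tests below were chosen after the results were seen: the circular shifts, the scaling of the shared gains, the division by the SD and the choice of loci that survive it.

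Loci that lost the mark in nrde-3 most sharply formed a small group. After each preparation was divided by its SD, 188 windows were still called lower in nrde-3 than in N2 by limma, 153 of them in 20 loci. Their mean log2 ratio before scaling was 2.86 in N2, 0.34 in nrde-3 and 0.72 in lin-61. The longest was II 2992501 to 3001500, at 3.37 in N2, 0.48 in nrde-3, 1.04 in lin-61, -0.17 in met-2 nrde-3 and 0.12 in lin-61 met-2. In the same order, the levels at X 16885665 to 16893164 were 2.96, 0.51, 0.76, -0.10 and 0.00. In 1 of the 20 loci met-2 nrde-3 was above 1: II 7081984 to 7085982 stood at 2.51 in N2, 0.09 in nrde-3, 2.12 in met-2 nrde-3, 0.64 in lin-61 and 1.44 in lin-61 met-2.

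The single windows with the largest change on each chromosome come from the same fit, so they illustrate the contrast of gains and losses without adding support. Between met-2 nrde-3 and nrde-3 the change was positive on I (8977963 to 8978462, 4.61 ± 0.36 SE), II, III, IV and X, where X 16384667 to 16385166 gained 4.08 ± 0.34, and negative on V (19963891 to 19964390, -4.25 ± 0.56). Between nrde-3 and N2 it was negative on all 6 nuclear chromosomes, with II 3306000 to 3306499 at -4.66 ± 0.36 and V 1691969 to 1692468 at -4.37 ± 0.26. Between lin-61 and N2 it was also negative on all 6, with V 17519401 to 17519900 at -4.53 ± 0.48.

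Most windows called lower in nrde-3 than in N2 may reflect a common factor per preparation, such as the yield of the immunoprecipitation. Of the 12510 windows called lower in the restricted set, 98.5% lost the call when each preparation was divided by its own SD. Their median change went from -0.97 (SE 0.27) to -0.42 (SE 0.23), so the call ended because the change shrank more than its error. A common factor alone is argued against for the 188 windows that were still called, at a median of -1.45 (SE 0.23) after -2.40 (SE 0.27). A loss spread over all marked windows of nrde-3 would give the same picture and stays open, as untested.

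For the windows that gained the mark on adding the met-2 mutation in both backgrounds, 2 technical explanations were examined. Shared position was compared with circular shifts, of which 0 of 1000 reached the 6769 observed, with 2804 as the highest. The shifts move calls between arms and centres, and their mean of 1578 was below the 2263 of independent lists within regions. They therefore cannot tell what shared arms or centres give. The 2263 takes these regions into account and also lies below 6769, while finer shared position was not tested. Losses on the arms could raise all other windows through the scaling, but a scaling factor moves all windows of a library alike. Windows gained in the other background exceeded those not called there by more in the double than in the single mutant, by 0.51 for met-2 nrde-3 and 0.36 for lin-61 met-2, and by 0.49 and 0.24 in autosome centres (SD between preparations at most 0.09). Other technical explanations, such as the input labels that cross, were not tested for these windows, and the table held no met-2 single mutant, so the cause stays open.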
